A study of Mus musculus with 4 samples.

How the data were processed

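RNA from single cells of the vagal ganglion complex of 5-week-old mice was measured in 4 droplet libraries, 2 from wild-type mice without sorting and 2 from Vglut2Cre-Tomato mice after fluorescence-activated cell sorting. Per the labels' protocols, the ganglia were digested with papain and a collagenase and dispase mix, strained and cleaned on a density gradient, and the libraries were made with the 10x Genomics Single Cell 3' v2 kit. This kit reads the 3' end of each transcript and marks every captured molecule with a unique molecular identifier (UMI). Cell Ranger 2.1.1, Seurat and the mm10 build are named per the submitters' processing notes, which do not say which step each served; filters on cells and genes, doublet removal and the clustering method are not given in the sources used here.

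The expression values were deposited as natural log values, ln(1 + UMI count per 10000 UMIs of the cell), for 17289 genes and 1825 cells. Undoing the log gave a sum of 10000 in every cell, and 100% of the non-zero values were whole UMI counts within a tolerance of 0.01, so the UMI count of each gene in each cell could be read back. A deposited annotation gave the library, the cluster, the total UMI count and the mitochondrial share of each cell. The authors deposited that mitochondrial share as a fraction of the cell's UMIs, and it differed from the share read back by at most 5e-16. The annotated UMI totals exceeded the totals read back by a median of 5 and at most 104 per cell. The series description states 1896 cells, 71 more than were analysed here. The lowest annotated UMI total was 6194, the lowest number of detected genes 2061 and the highest mitochondrial share 24.9%. All value columns were used. No cell was removed and no doublet caller was run; cells in the highest 5% of UMI counts were left out as an alternative.

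Cell classes were taken from the deposited cluster names: 18 NG clusters were read as nodose neurons, 6 JG clusters as jugular neurons, and satellite glia, endothelial and sympathetic clusters by their names. Naming each cell by fixed marker genes gave the same class for 1420 of 1459 nodose neurons, 245 of 245 jugular neurons, 51 of 51 satellite glia and 50 of 51 endothelial cells, but for only 2 of 19 sympathetic neurons, of which 16 were named nodose.

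The linear values (UMIs per 10000 UMIs) were averaged per library and class, so that a library and not a cell was the replicate. A profile needed at least 10 cells. Genes with a mean above 0.1 per 10000 in at least as many profiles as the smaller group were tested with limma 3.58.1 with a mean-variance trend (R 4.3.3) on log2(mean + 1), two-sided, with Benjamini-Hochberg adjustment within each fit. Every fold change is therefore on the log2(value + 1) scale, which understates the change of low genes. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The library was a block for neurons against non-neuronal cells, nodose against jugular neurons and each type against the other neurons of its ganglion; sorted against unsorted neurons was fitted without a block. A fit on summed raw counts had been planned for a deposit of raw counts. The values are normalized, so the test planned for normalized values was used, and limma-voom on the UMIs read back was run as an added alternative.

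The groups, tests, thresholds, gene lists, marker lists and the rule for named genes were set before the data were examined. The rule named the 6 largest folds in each direction among called genes that moved the same way in every library, 10 genes in any case (among them Prdm12, P2rx2, Wfdc2, Slc17a6, Trpv1, Piezo2, Scn10a, Calca and Tac1), and up to 3 called members of each fixed list with the smallest adjusted p. For each type it named the 2 list genes and the 1 gene overall with the largest rise; for sorted against unsorted neurons the 6 largest folds in each direction and Slc17a6. The 19 lists cover transmitters, neuropeptides, ion channels, receptors, neurofilaments, Hox genes, sensory transcription factors and the dissociation response. Genes of types with too few cells for a test were picked by size after the data were seen. Some genes that these rules named, and an alternative that rests on them, are not reported here.

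Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 allows up to 3 cells or counts; both cover counting error only. For shares of cells with a UMI of a gene, each cell was also thinned to 10000 UMIs, which left out 18 nodose, 2 jugular, 28 satellite glial and 31 endothelial cells. The fits were tested on simulated data with 200 changed genes each, drawn from genes above 1 UMI per 10000, with a single dispersion of 0.02. For sorted against unsorted neurons the simulated levels held no difference between libraries. Changed genes of lower level and larger spreads were not simulated, so the shares below describe this simpler case. For nodose against jugular neurons (8601 genes run), 100% of genes changed 2-fold and 4-fold reached an adjusted p under 0.05, and 7% and 73% also passed the fold threshold. For neurons against non-neuronal cells the shares past both were 4% and 76%, for sorted against unsorted neurons 8% and 67%, and for type NG14 6% and 78%. No unchanged gene passed both in any of these fits. The threshold thus left out most genes changed 2-fold and part of those changed 4-fold. On the log2(mean + 1) scale a 2-fold change stays below 1, and a 4-fold decrease of a low gene can too.

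Alternatives set at the same time were median centring, no filter on low genes, no trend, pseudocounts of 0.1 and 10, leaving out each library, minimums of 5 and 20 cells, no library block, thinned cells, and sorted or unsorted libraries alone. Limma-voom, rescaling to non-mitochondrial UMIs and equal weights for types were added later. Of the gene symbols, 16707 (96.6%) were found in GENCODE M21, which uses the same mouse assembly as mm10 and gave the coordinates. The end of each transcript (500 nt) was searched with BLAST 2.17.0 for matches of at least 95% identity over 90 nt at another gene. Computations outside R used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.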

Results

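Single-cell transcriptomes were collected from the vagal ganglion complex, which holds the nodose and jugular ganglia with the cell bodies of the vagus nerve's sensory neurons. The tables held 1825 cells in 27 clusters. Wild-type C57BL6 mice gave 2 libraries of unselected cells (wild-type unsorted 1 and 2), with 270 and 930 cells. Mice in which Cre from the Slc17a6 (Vglut2) locus turns on the red protein tdTomato gave 2 sorted libraries (Vglut2Cre-Tomato sorted 1 and 2), with 328 and 297 cells. In that order the libraries held 16147719, 30778125, 17887507 and 17361999 UMIs, with medians of 63793.5, 33395, 53574 and 54929 UMIs per cell. The labels do not say how many animals a library holds, so p-values measure the spread between these libraries, which may be partly technical. Limma takes part of that spread from other genes.

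The first question was which cells the preparations held. Nodose neurons made up 1459 cells and jugular neurons 245, and the rest were 51 satellite glia, 51 endothelial cells and 19 sympathetic neurons. Satellite glia and endothelial cells together were 13.7% of unsorted library 1 (95% interval 9.84 to 18.4) and 6.56% of unsorted library 2 (5.05 to 8.35). They were 1.22% of sorted library 1 (0.333 to 3.09) and 0 of 297 cells of sorted library 2, which allows a share of up to 1.01%. Sympathetic neurons, a type without glutamate release, numbered 11 and 8 in the unsorted libraries and 0 in both sorted ones. Jugular neurons were 15.3% (10.8 to 20.7) and 15.8% (13.4 to 18.4) of the sensory neurons in the unsorted libraries, and 7.72% (5.06 to 11.2) and 16.8% (12.8 to 21.6) in the sorted ones. With 2 libraries against 2, an exact permutation test cannot go under 0.333, so no test was made. The sort, the genotype and the library batch can each set these shares and cannot be told apart.

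**Figure D1:**
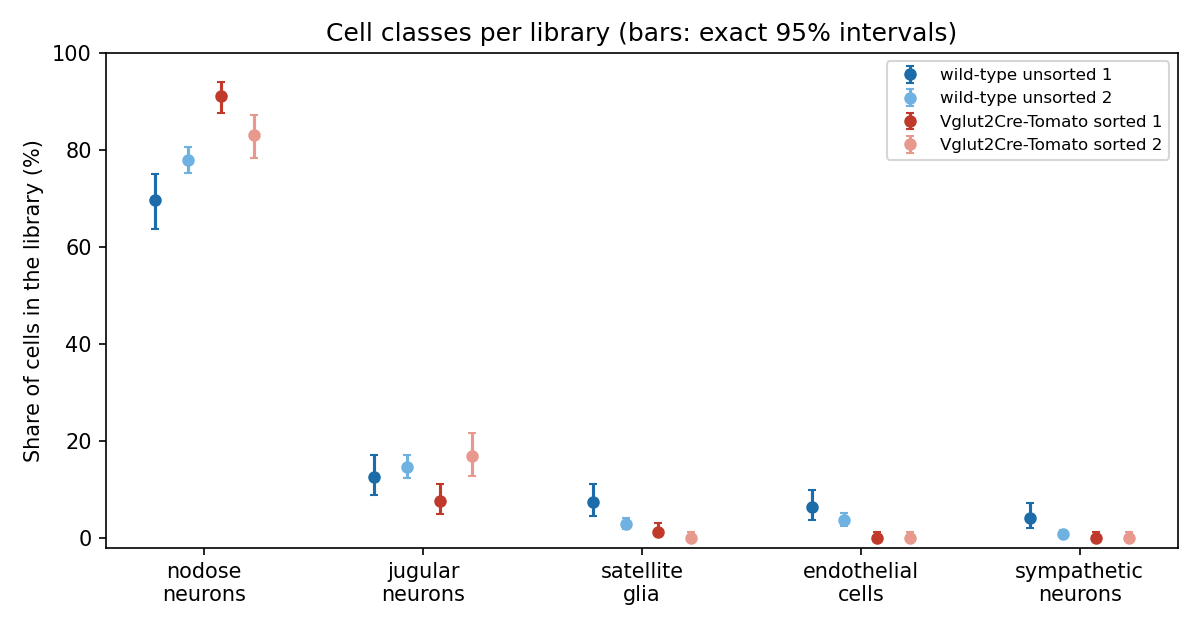
Share of cells in each library (y axis, percent) for the 5 cell classes (x axis); points are single libraries, blue for wild-type unsorted and red for Vglut2Cre-Tomato sorted, and bars are exact 95% intervals. Satellite glia and endothelial cells lie at or below 1.22% in the sorted libraries, and jugular neurons overlap between the preparations.

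Nodose neurons, which arise from the placodes and carry most visceral sensation, were compared with the crest-derived jugular neurons in each library. Transcripts of Hoxb5, a homeobox factor, were at 4.99 ± 1.15 UMIs per 10000 in nodose and 0.0966 ± 0.0345 in jugular neurons (mean ± SD, n = 4 libraries; log2 fold change 2.43, SE 0.09). Htr3a, a subunit of the serotonin-gated channel, was 2.30 higher on the log2 scale, P2rx2, an ATP-gated channel, 2.26, Lypd1 2.25 and the neurotrophin receptor gene Ntrk2 2.17. Jugular neurons were richer in Calca, which encodes the peptide CGRP, at 31.2 ± 17.7 against 0.963 ± 0.722 (log2 fold change -3.96, SE 0.15), and in Tac1, the substance P precursor, at 16.5 ± 5.51 against 1.10 ± 0.466 (-3.04, SE 0.12). S100a6 (-3.14), Rgs10 (-3.02), Tmem233 (-2.59) and Fxyd2 (-2.33) followed. Limma called 112 of 8833 genes, 52 higher and 60 lower in nodose neurons, and 3911 genes had an adjusted p under 0.05 at any fold. The clusters were drawn from these same transcripts, so the p-values show how evenly the 4 libraries carry a difference and are not independent evidence for the classes.

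Transcription factors of sensory neurons were looked at next. Prdm12, a regulator of nociceptor development (chromosome 2, 31640037 to 31655795, plus strand), was at 0.00369 ± 0.00194 in nodose and 1.65 ± 0.586 in jugular neurons (log2 fold change -1.37, SE 0.10, adjusted p = 5.12e-06 by limma). Of 20 tested sensory transcription factors, 3 were higher in nodose neurons (among them Tbx3 and Etv1), 5 were lower (Prdm12, Prrxl1, Pou4f1, Isl2 and Runx1) and 12 were not called. Of 6 tested Hox genes 1 was higher, Hoxb5. Tbx3 sat at the fold threshold and was at 0.96 without unsorted library 2. Wfdc2, a fixed marker of jugular neurons, was not called at -0.48, with 0.403 ± 0.167 in jugular and 0.00117 ± 0.00112 in nodose neurons. It was called with a pseudocount of 0.1 (-2.24) and with limma-voom (-8.25). Within the jugular neurons its mean over 4 libraries was 3.23 in type JG1 (24 cells, not tested) and 0.0169 in the others.

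Among the peptide genes, 1 of 13 tested was higher in nodose neurons (Vip) and 4 were lower (Tac1, Nmb, Calca and Calcb). Of 8 mechanosensitive and acid-sensing channels, Tmc3 was higher (1.38) and Piezo2, the mechanically gated channel, lower (-1.02, 0.494 ± 0.0325 against 2.03 ± 0.0948). Tmc3 was under the fold threshold in the unsorted libraries alone (0.92). Sodium channels gave 1 lower gene of 13, Scn11a (-1.17). Scn10a went the same way but was under the fold threshold at -0.86 (1.31 ± 0.168 against 3.23 ± 0.630). Its adjusted p by limma was at most 0.00115 in 20 settings, and it was called with a pseudocount of 0.1 (-1.23) and with limma-voom (-1.22). Receptor lists held 1 higher gene each among 6 purinergic (P2rx2), 4 serotonin (Htr3a), 6 gut hormone and metabolic (Cckar, the cholecystokinin receptor, 1.58) and 5 acetylcholine receptors (Chrna3, 1.29). Neurotrophic factor receptors split, with 2 higher (Ntrk2 and Ngfr, 1.53) and 2 lower (Gfra3, -1.31, among them) of 9. Inflammatory mediator receptors also split, F2r, the thrombin receptor, being higher (1.69) and Lpar3 lower (-1.06) among 15. Lpar3 lost its call without sorted library 1, at -0.88, and in the unsorted libraries alone, at -0.77. Mrgprd was the 1 lower gene of 2 Mrgpr receptors (-1.43), and Kcnq3 the 1 higher of 28 potassium and HCN channels (1.28).

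No gene was called among 5 transmitter genes, 9 TRP channels, 8 GABA and glycine receptors, 2 opioid and cannabinoid receptors, 7 neurofilament and large-fibre genes and 13 dissociation response genes. Limma gave an adjusted p under 0.05 at smaller folds for 5, 4, 6, 2, 3 and 8 of them. Counts adjusted over the list alone were equal for all 19 lists. Slc17a6, the vesicular glutamate transporter, was at 2.67 ± 0.277 in nodose and 2.02 ± 0.379 in jugular neurons (0.29, not called), and Trpv1, the capsaicin receptor, at 1.06 ± 0.172 and 1.48 ± 0.344 (-0.26, not called). The mitochondrial transcript mt-Nd5 was higher in nodose neurons (1.82), whose median mitochondrial share was 7.91%, 7.60%, 6.82% and 8.34% in the libraries, in the order given first, against 4.12%, 4.28%, 3.81% and 5.45% in jugular neurons. Transcripts of the glial gene Apoe were at 10.3 ± 10.4 in nodose and 4.72 ± 4.70 in jugular profiles (0.71, not called).

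**Figure D2:**
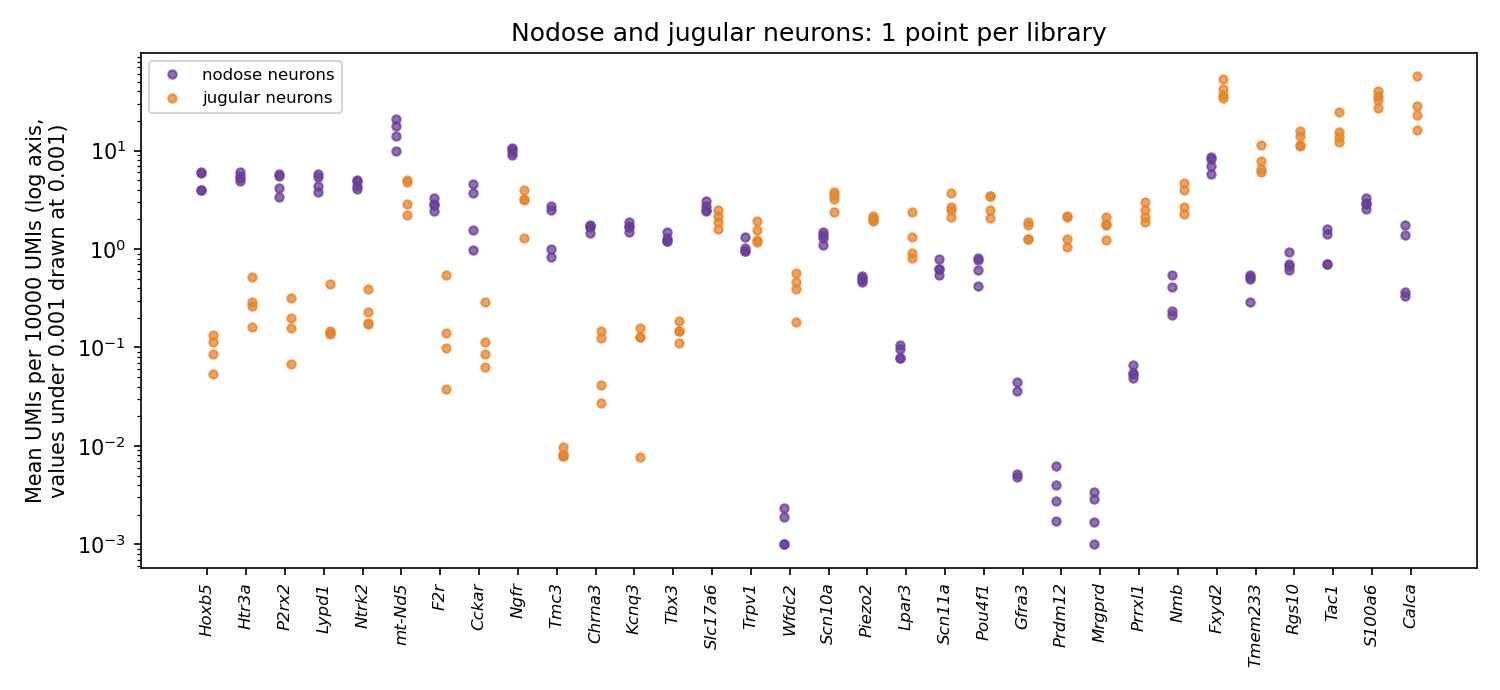
Mean UMIs per 10000 UMIs (y axis, log scale) of named genes (x axis) in nodose (purple) and jugular neurons (orange), 1 point per library; values under 0.001 are drawn at 0.001. The pools separate in every library for genes such as Hoxb5 and Calca and overlap for Slc17a6 and Trpv1.

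Each nodose or jugular type was then compared with the other neurons of its ganglion, to show which receptors, channels and peptides mark it. NG13 carried 26.4 ± 9.97 UMIs per 10000 of Cckar against 1.40 ± 0.430 in other nodose neurons (log2 fold change 3.46, SE 0.12) and more of the peptide gene Cartpt (2.38). NG17 carried Gpr65, a proton-sensing receptor, at 3.80 ± 1.46 against 0.0695 ± 0.0277 (2.11, SE 0.15), and Htr3a (1.73). NG15 was high in Vip (1.95), Htr3a (1.92) and Pkib (2.27), NG14 in Gal, which encodes galanin (1.42), and Adcyap1 (1.32), and NG16 in Trpa1, an irritant-gated channel (1.38). NG1 was high in Lypd1 (2.59), the purinergic receptor P2ry1 (2.34) and Gabra2 (1.65), and NG12 in S100a11 (2.31), Trpa1 (1.26, and 0.95 with a minimum of 5 cells) and Htr3a (1.14). Trpa1 was called higher in NG15 too. Among jugular types JG2 could be tested, and carried Mrgprd at 5.78 ± 1.44 against 0.120 ± 0.0670 (2.58, SE 0.12) and Lpar3 (2.21). Limma made 942 calls over 14 types, 444 higher and 498 lower in the type, from 30 in NG16 to 138 in JG2. A gene called in several types is counted once for each.

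Types NG8 and NG11 had no called higher gene among the receptor, channel and peptide lists, with 11 and 14 lower ones of 109 and 113 tested. NG8 was led by Gda (2.20, 6.04 ± 1.47 against 0.512 ± 0.146) and NG11 by Lypd1 (3.17, 30.9 ± 1.65 against 2.61 ± 0.806). NG9 had Tmc3 (1.19) and Lamp5 (1.56), NG7 Gal (1.79), Tac1 (1.61) and Pcdh9 (2.04), and NG18 Scn10a (1.33), Chrnb3 (1.10) and Dcdc2a (1.67). NG13 had 10 higher and 0 lower list genes of 113, and NG1 12 higher and 11 lower of 124, its higher ones including Piezo2, Ntrk3 and Kcna1. NG1, NG4 and NG12 rest on 2 libraries and JG2, NG7, NG9, NG13 and NG18 on 3, where limma borrows nearly all of the spread from other genes. Calca was called in NG16 (1.33) and NG4 (1.43), but was at 0.73 in NG16 without sorted library 2. Without the library block Calca in both, Gal in NG14, Tac1 in NG7 and Tmc3 in NG9 lost their calls (adjusted p = 0.178, 0.165, 0.0669, 0.0561 and 0.237 by limma). Without the filter on low genes so did Calca in NG16, Gal, Tac1 and Pcdh9 in NG7 and Tmc3 in NG9 (0.123, 0.0567, 0.0838, 0.0552 and 0.0689), and Tmc3 was at 0.96 in NG9 without sorted library 1.

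The other 10 types had too few cells for a test and are given as values over 4 libraries. Among jugular types, JG1 held P2ry1 at 6.13 ± 3.77 against 0.0998 ± 0.0755 in other jugular neurons and Piezo2 at 7.61 ± 1.74 against 1.29 ± 0.389. JG3 held the peptide gene Sst at 4.05 ± 0.815 against 0.00520 ± 0.00552, with Osmr (2.73 ± 0.164) and Il31ra (2.14 ± 0.578), subunits of the receptor for interleukin 31. JG4 was the peak of Calca at 131 ± 136 against 12.4 ± 4.89, with Tac1 at 58.4 ± 46.5; sorted library 1 has 3 JG4 cells, and over all 66 cells Calca was at 75.6 and Tac1 at 35.1. JG5 held Thy1, Kcna1, Asic3 and Ngfr, the first at 14.4 ± 2.12 against 0.491 ± 0.318, and JG6 held Hjurp, Pcp4 and Scn7a. Among nodose types, NG2 held neurofilament Nefh at 25.4 ± 3.94 against 3.07 ± 0.552 with Kcna2 and Kcnk1, NG3 held Tmem233 and Piezo2 (3.94 ± 1.77 against 0.433 ± 0.0187), and NG5 held Tac1 at 26.9 ± 9.78 against 0.635 ± 0.260. NG6 held Ptn at 19.2 ± 12.9 against 1.22 ± 0.299 and NG10 held Ntrk3 at 5.25 ± 0.979 against 0.247 ± 0.00835. P2ry1, high in NG1, was also high in NG3 (4.38 ± 3.32 against 0.514 ± 0.355) and NG10 (2.98 ± 1.48 against 0.565 ± 0.412). Lypd1, high in NG1 and NG11, was at 27.0 ± 5.05 against 4.56 ± 1.03 in NG10. All these genes were higher in the type in 4 of 4 libraries.

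Shares of cells with a UMI traced the same genes, with endothelial cells as the class that should lack them (median 9670 UMIs per cell, against 45981.5 in NG17, 43992 in NG13 and 54809 in JG2). Gpr65 was found in 77.3% of 110 NG17 cells (exact 95% interval 68.3 to 84.7), 5.63% of other nodose neurons and 0 of 51 endothelial cells, and in 69.4% of NG17 cells thinned to 10000 UMIs. Mrgprd was found in 97.1% of 70 JG2 cells (90.1 to 99.7) and 9.71% of other jugular neurons. Cckar was found in 100% of 95 NG13 cells (96.2 to 100) against 57.3% of other nodose neurons and 9.80% of endothelial cells, and thinning left 100% against 37.0%. Ptn, which leads NG6, had UMIs in 100% of 27 NG6 cells and 70.8% of other nodose neurons, and thinning left 100% against 42.9%. It also had UMIs in 98.0% of endothelial cells and 100% of satellite glia, so its share does not separate NG6 from those classes. Sst was found in 43.3% of 30 JG3 cells (25.5 to 62.6) and 3.26% of other jugular neurons.

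**Figure D3:**
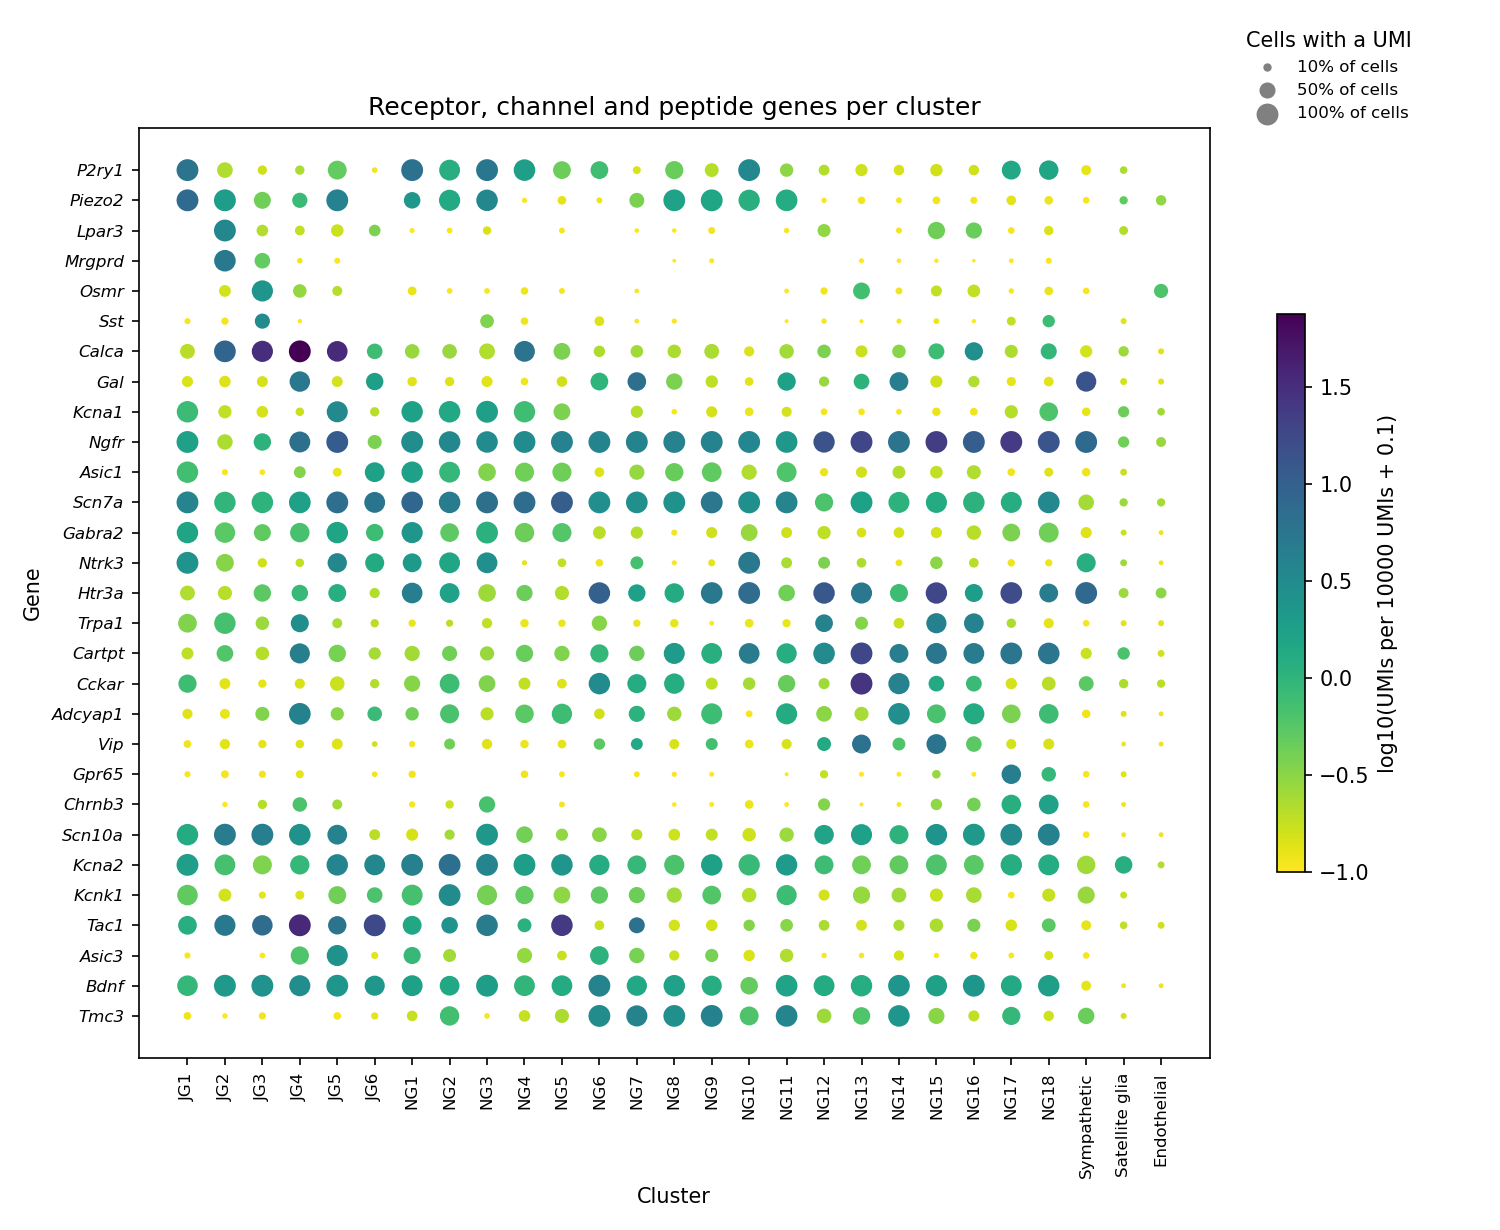
Receptor, channel and peptide genes (y axis) in the 27 clusters (x axis); dot area gives the share of cells with a UMI and colour the log10 of mean UMIs per 10000 UMIs plus 0.1. Cckar peaks in NG13, Gpr65 in NG17 and Mrgprd in JG2.

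Neurons were compared with the pooled satellite glia and endothelial cells of the 2 unsorted libraries, the libraries that held enough of both. Snhg11, a small nucleolar RNA host gene, was at 20.7 ± 0.912 in neurons and 0.553 ± 0.415 in non-neuronal cells (mean ± SD, n = 2 libraries; log2 fold change 3.83, SE 0.15). Meg3 (3.78), Pcsk1n (3.61), Stmn2 (3.59), Prph (3.50) and Syt4 (3.46) followed. Non-neuronal cells were richer in Cldn5, a tight junction gene of endothelium, at 22.8 ± 0.507 against 0.0179 ± 0.00542 (-4.55, SE 0.10), and in Igfbp7 (-4.49), Apoe (-4.40), Sparc (-4.07), Ifitm3 (-4.06) and the glial gene Fabp7 (-4.02). Limma called 836 of 9807 genes, 508 higher and 328 lower in neurons. All 7 tested neurofilament and large-fibre genes were higher in neurons, with Prph, Fxyd7 (2.29) and Nefh (1.96) among them. Of 15 dissociation response genes 9 were lower in neurons and 0 higher, with Junb (-3.78), Egr1 (-3.28) and Fos (-3.03) at 1.95 ± 0.0383, 2.09 ± 0.345 and 4.24 ± 0.387 in neurons and 39.7 ± 3.23, 29.2 ± 6.38 and 42.1 ± 8.29 in the other cells.

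Channel and receptor genes that were called in this comparison were all higher in neurons. They numbered 5 of 13 sodium channels (such as Scn9a, 1.84, and Scn7a, 1.58), 5 of 24 potassium and HCN channels (Kcnb2, 2.26), 1 of 9 TRP channels (Trpv1, 1.05, and 0.98 with median centring), 0 of 9 mechanosensitive and acid-sensing channels, 1 of 9 purinergic, 1 of 3 serotonin, 1 of 7 gut hormone and metabolic, 1 of 16 inflammatory mediator, 0 of 2 Mrgpr, 2 of 9 neurotrophic factor (Ngfr, 3.05, and Ret, 1.78), 1 of 5 acetylcholine, 1 of 9 GABA and glycine and 0 of 2 opioid and cannabinoid receptors. Of 10 peptide genes 4 were higher (Bdnf, Tac1, Calca and Cartpt), of 5 transmitter genes 2 (Slc17a6, 1.75, and Nos1, 1.20), of 8 Hox genes 1 (Hoxb5, 2.49), and of 20 transcription factors 5 were higher and Maf was lower. Counts adjusted over the list alone were equal for every list. At any fold, limma gave an adjusted p under 0.05 for more channel and receptor genes. Higher in neurons were 13, 23, 7, 7, 5, 3, 4, 10, 2, 7, 5, 8 and 2, in the order of lists above. Lower were 1 TRP channel, 2 mechanosensitive and acid-sensing channels and 4 purinergic receptors. So were 1 gut hormone and metabolic, 5 inflammatory mediator and 1 GABA and glycine receptor. Neurons held more UMIs per cell than the other cells, with a median of 9930 in satellite glia and 9670 in endothelial cells. The profile of the other cells mixes satellite glia, at 796 ± 153 UMIs per 10000 of Apoe, with endothelial cells, at 7.35 ± 0.485.

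Neurons of the sorted libraries were compared with those of the unsorted libraries, a comparison of 2 libraries against 2. With so few libraries limma borrows much of the spread from other genes, and the small adjusted p-values below rest on this. Pfn1, the actin-binding profilin, was at 5.42 ± 1.05 in sorted and 0.374 ± 0.174 in unsorted neurons (n = 2 libraries each; log2 fold change 2.22, SE 0.12, adjusted p = 1.03e-06 by limma). Calm3, a calmodulin gene (1.65), the class I histocompatibility gene H2-D1 (1.44), Clu (1.35), Gm8797 (1.30) and the ubiquitin gene Ubb (1.28, and 0.96 without unsorted library 2) were also higher. Apoe was lower in sorted neurons, at 1.26 ± 0.926 against 17.6 ± 1.60 (-3.10, SE 0.22, adjusted p = 4.43e-06), as were the glial gene Fabp7 (-1.43) and Sparc. Limma called 36 of 8912 genes, 13 higher and 23 lower, and of the 23 lower ones 14 encode ribosomal proteins, with Rpl39 (-1.36), Rps27 (-1.35) and Rps29 (-1.33) first. Of 98 tested ribosomal protein genes 89 were below 0, with a median of -0.56, and limma gave an adjusted p under 0.05 for 62 lower and 5 higher ones, of which 0 were called higher. The mitochondrial transcripts mt-Atp8 (-1.12) and mt-Nd3 (-1.01) were called lower too, while mt-Co3 was at 0.49, not called. Slc17a6, whose locus drives the Cre, did not differ detectably, at 2.48 ± 0.183 and 2.68 ± 0.384 (-0.08, SE 0.11, adjusted p = 0.646).

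Within the fixed lists 1 gene was called, the gut hormone receptor gene Cckar, lower by a log2 fold change of -1.10 (SE 0.12) from 3.52 ± 0.516 in unsorted neurons, and the other 18 lists gave 0. NG13, the type richest in Cckar, was 2.78% and 3.37% of sensory neurons in the sorted libraries and 7.66% and 6.85% in the unsorted ones. How much of the fall in Cckar these shares make was not tested. In nodose neurons alone 38 genes were called (14 higher, 24 lower), with Gal higher and the globin gene Hbb-bs lower, and in jugular neurons 37 (16 higher, 21 lower), with Lgmn (1.32) and Tubb2a (1.29) higher and Basp1 (-1.53), Rps21 and Rps12 lower. All 37 jugular calls were lost without the filter on low genes. The adjusted p by limma was then 0.137 for Lgmn, Tubb2a and Rps12 and 0.145 for Basp1 and Rps21. Tubb2a, Basp1 and Rps21 also lost their calls without either sorted library. In jugular neurons 1 peptide gene was higher when adjusted over the list alone and 0 over all genes. Vps8 (-1.85) and Hbb-bs rest on unsorted library 2, where nodose neurons held 11.4 and 5.17 UMIs per 10000, and were at -0.71 in neurons and -0.20 in nodose neurons without it. Genotype, sort and library batch cannot be told apart here, and without 1 sorted library 11 genes were called in nodose and 9 or 11 in jugular neurons.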

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

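The tests in this part were chosen after the values were seen, with these exceptions. The test of the Slc17a6 level was set out before, and the comparison of the nodose-jugular difference between preparations follows from the design. The tests of free glial RNA and of captured glia took their final form, on 3 genes, after the values were seen.

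The nodose-jugular difference of Tmc3 was larger in the sorted than in the unsorted libraries, by 0.93 on the log2 scale (adjusted p = 0.0448 by limma; 1.85 and 0.92). Nodose neurons held 2.51 and 2.76 UMIs per 10000 of Tmc3 in the sorted libraries and 0.991 and 0.827 in the unsorted ones, and jugular neurons held under 0.01 in each, so the change lies in nodose neurons. Types rich in Tmc3 had larger mean shares in the sorted libraries (ratios of means 1.63 for NG9, 1.64 for NG11 and 1.41 for NG7), but the shares of all types, at the Tmc3 level of each type in the unsorted libraries, gave 0.974 and 1.09 in the sorted libraries and 0.854 and 0.863 in the unsorted ones. The difference of the glial gene Fabp7 was smaller in the sorted libraries, by -0.73 (adjusted p = 0.0448; 0.08 and 0.81). Of 8833 genes, 4 had an adjusted p under 0.05 for this difference (with Ndrg2 and Lxn), 0 of them at a size of 1 or more, and 1022 had an unadjusted p under 0.05. The rule on a single library far from the others could not be applied, since each preparation has 2 libraries.

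Glial transcripts were lower in neurons of the sorted libraries, Apoe at 1.26 against 17.6 UMIs per 10000. Free glial RNA would reach endothelial droplets too, but UMIs of Fabp7, Kcnj10 and Sox10 per endothelial cell were 0.0314 (bootstrap 95% interval 0.00957 to 0.0626) and 0.129 (0.00762 to 0.363) of those per neuron in the unsorted libraries, which argues against free RNA as the main source. UMIs of these genes varied far beyond counting between nodose neurons, with a variance over mean of 33.1 and 25.1 in the unsorted libraries, at 12.5 and 8.44 UMIs per cell. The sorted libraries had ratios of 35.4 and 10.9, at 0.980 and 0.340 UMIs per cell, so the ratio does not separate the preparations. It cannot decide here, since capture with fewer neurons can leave the ratio unchanged, and glial cells or fragments captured with single neurons stay open. UMIs of these genes were found in 81.9% and 54.8% of nodose neurons in the unsorted libraries and 15.7% and 10.9% in the sorted ones. A difference in glial wrapping between the genotypes was not tested.

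The 32 other genes that differed between sorted and unsorted neurons, without 4 lower ones that were also lower in neurons than in other cells, form the second pattern, among them 14 ribosomal protein genes. A first test of reads shared between near-identical copies gave an odds ratio of 21.7 (18 of 32 called genes against 483 of 8629), but it mixed in abundance and ribosomal genes and was replaced. Called ribosomal protein genes had a copy in 11 of 14 cases and the other tested ones in 57 of 84 (odds ratio 1.74, 95% interval 0.409 to 10.4, Fisher's exact p = 0.541), so shared reads cannot be told apart from other causes for them; of 18 other called genes 38.9% had a copy, against a median of 5.56% and a 95th percentile of 22.2% in 10000 sets matched on level (p = 0.00020), which is consistent with read sharing for some of them (Ckb, Eno1, Gm8797, H2-D1, Tubb2a, Ubb and mt-Nd3). A trend with depth is argued against as the main cause by the last of 3 forms of its test: neurons of the sorted libraries had median UMI counts (53688 and 54929) between those of the unsorted ones (68224 and 34352), so a trend that only rises or only falls makes at most 0.5 of the difference between the unsorted libraries, a median of 0.143 of the fold (bootstrap 95% interval 0.0741 to 0.169; 0.614 for Vps8 and under 0.5 for the other 31, with 1 of 33 genes of this fold not called). Strain background, the sort and library batch follow the same split and stay untested.

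Types had unequal shares in the preparations, the third pattern. Both sorted libraries lay below both unsorted ones for JG4, NG1, NG12, NG13, NG16 and NG17 (ratios of means 0.426, 0.426, 0.428, 0.423, 0.866 and 0.537) and above for NG4, NG5, NG7, NG9, NG14 and NG15 (1.99, 1.40, 1.41, 1.63, 1.27 and 1.49); with 2 libraries against 2, chance alone puts a type in either group with a permutation probability of 0.333, and 12 of 24 types did so. Across 24 types the ratio correlated with the Slc17a6 level by Spearman's rho of 0.240 (permutation p = 0.255; Pearson's r 0.209, p = 0.326), and with the median UMI count by -0.248 (p = 0.241; r -0.158, p = 0.464). Ratios from separate pairs of libraries correlated by 0.239 (p = 0.262; r 0.239, p = 0.259) and in the crossed pairing by 0.372 (p = 0.0742; r 0.300, p = 0.155); over these 4 relations the adjusted p was 0.262 for each rho, and without the 2 farthest types r was 0.210, -0.361, 0.368 and 0.424. The Slc17a6 level and the RNA content stay undecided with 24 types. The correlations cannot decide on counting noise, since small and large types weigh the same. Exact 95% intervals were apart for NG12 (4.04 to 7.19% in unsorted library 2, 0.549 to 3.88% in sorted library 2). So were those of NG17 in these libraries (6.39 to 10.2% and 1.63 to 6.10%). NG15 had 5.26 to 8.75% in unsorted library 2 and 9.77 to 17.5% in sorted library 1. NG13 had 5.26 to 8.75% in unsorted library 2 and 1.28 to 5.21% in sorted library 1, and JG4 3.84 to 6.93% and 0.191 to 2.68%. NG11 had 3.44 to 6.40% in unsorted library 2 and 8.06 to 15.6% in sorted library 2. Each of these types was apart in the pair of libraries given and overlapped in the other pairs across preparations. These values, picked afterwards, argue against counting noise as the only source of the differences within those pairs. They leave it open for the other types.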

How the results depend on the processing

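Limma-voom, rescaling to non-mitochondrial UMIs and equal weights for types were chosen after seeing the data; the other alternatives were planned. Calls depended strongly on the pseudocount and on the test. The count over types is for neuron types against the other neurons of their ganglion: genes past the threshold, added up over the types tested. With 0.1 the counts were 739 for nodose against jugular, 4114 for neurons against non-neuronal cells, 7322 over types, and 172, 183 and 209 for sorted against unsorted neurons, nodose and jugular neurons. With 10 they were 6, 46, 31, 1, 1 and 0, and with limma-voom, which also changes the weights and the summing, 2417, 5703, 20264, 678, 753 and 260. All 112 nodose-jugular calls remained with 0.1 and with limma-voom. No called gene changed sign in any of these comparisons and settings. Over types, a minimum of 5 cells gave 2047 calls in 23 types and of 20 cells 282 in 6 types. Without the filter on low genes jugular neurons gave 0 calls between preparations, NG7 0 in place of 47 and NG4 41 in place of 80; the cause was not tested.

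The same sum is used here for neuron types against the other neurons of their ganglion: genes past the threshold. Leaving out each library gave 107 to 123 calls for nodose against jugular, from 633 in 11 types to 922 in 14 over types, and 29 to 53, 11 to 55 and 9 to 54 for sorted against unsorted neurons, nodose and jugular neurons; the lone library is then assumed to vary like the others. Neurons against non-neuronal cells could not be tested in this way, since the comparison holds 2 libraries and 1 gives no fit. Trpv1 turned from -0.26 to 0.011 with limma-voom (adjusted p = 0.969). Slc17a6 between preparations, not called, turned to 0.030 and 0.021 in neurons and nodose neurons without unsorted library 2 and to 0.0029 in jugular neurons without sorted library 1; it was -0.183 and -0.184 without unsorted library 1 and -0.288 without sorted library 2. The jugular share of unsorted sensory neurons moved from 15.6% to 15.2% without the cells of most detected genes and to 16.3% with marker-named cells. Thinning moved 26 of 57 shares of cells with a UMI by more than their SD over libraries. Equal weights gave 40 calls and non-mitochondrial rescaling 120. No paired analysis was possible because the labels give the preparations no shared replicate numbers.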

Other observations

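The tests of other splits of the profiles were set out before the results were seen, and no other test is reported in this part.

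Sympathetic neurons, which enter no comparison, were found in the unsorted libraries alone, 11 and 8 cells. They carried the noradrenergic genes Dbh at 19.4 ± 3.67, Th at 8.62 ± 1.76 and Slc18a2 at 6.47 UMIs per 10000 (mean ± SD, n = 2 libraries), the peptide gene Npy at 39.5 ± 16.2 and the factor Hand2 at 6.52 ± 1.11. Htr3a was at 7.10 ± 3.35, while Slc17a6 was at 0.0720 ± 0.00936 and P2rx2 at 0.178 ± 0.0993. Satellite glia carried Fabp7 at 97.5 ± 0.539. Endothelial cells carried Cldn5 at 45.1 ± 5.16, Flt1 at 17.1 ± 0.0770 and Rgs5, a gene of mural cells, at 8.18 ± 0.530.

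Other splits of the profiles into groups of equal size, fitted without the library block, were counted for each comparison with at least 3 profiles a side. The classes were drawn from these same transcripts, which favours the real split, so a higher count for it does not exclude chance. For nodose against jugular neurons the real split gave 112 genes and the highest of the other 34 gave 31, and 1 of 35 splits reached the real count. The counts were 70 against 32 for NG11, 52 against 37 for NG15, 28 against 24 for NG16 and 47 against 27 for NG8, with 1 of 35 splits each. For NG14 (33 against 41) and NG17 (48 against 62), 2 of 35 splits reached the real count. In all these cases the highest other split was that of sorted from unsorted libraries, and the fits with the library block gave 34 genes for NG14 and 49 for NG17. JG2, NG13, NG18, NG7 and NG9 have 10 splits each, too few for a share under 0.05, with 138, 51, 40, 41 and 40 genes and 0 in the highest other split. Swapping profiles within libraries for nodose against jugular neurons makes 8 splits, also too few, with 112 genes and 0 in the highest other.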
